A study of Mus musculus with 2 samples.

How the data were processed

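Gene expression was measured in white adipose tissue of mice with hybridisation arrays, 1 array labelled as a control mouse and 1 as a mouse deficient in Oma1. Whether an array held RNA of 1 mouse or a pool is not given in the labels. Per the labels, total RNA was extracted with Trizol, biotin-labelled and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, a design that probes each transcript along its whole length. The authors deposited 1 intensity per probe set and array, on a linear scale and rounded to whole numbers. The software, the background correction, the summary of probes into probe sets and the scaling between arrays are not given in the sources used here. The deposited intensities ran from 8 to 21216 in the wild-type array and from 8 to 21365 in the Oma1-deficient array. Both arrays had a median of 83 over the 35512 probe sets. The upper quartiles were close but not equal, at 335 and 318. Rounding makes the values of the dimmest probe sets coarse, and such signals cannot be told from background here, since no detection call was used.

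Probe sets were named from GEO's platform annotation. A single gene symbol was given for 21789 probe sets, several for 1621 and none for 12102. Of the single-symbol probe sets, 21698 had a gene identifier that matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols differed from it. No coordinates are printed, since no genome build is stated for the array values. The 21789 probe sets named 19938 genes, of which 999 had more than 1 probe set. Probe sets with several symbols or none entered no gene-level value.

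Intensities were put on a log2 scale after a pseudocount of 1, which understates the change of dim genes. Probe sets of 1 gene were averaged on that scale. Every difference is the log2 value in the Oma1-deficient array minus that in the wild-type array. No further normalisation was applied. Genes were counted and ranked if their mean over the 2 arrays was at or above the median of all probe sets, an intensity of 83, which 11399 genes passed (57.2%).

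With 1 array per group no test of the genotype is possible, and no p-value is given. The spread between animals was not measured. Differences were described by fixed sizes of 2-fold and 1.5-fold. The technical spread was estimated from the 545 genes that passed the filter and had exactly 2 probe sets. The SD between probe sets of one gene was 0.17 on the log2 scale. It covers disagreement between probe sets on the same 2 RNAs and nothing else.

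Gene lists for pathways and cell types were fixed before the data were examined, as were the sizes, the filter and the rule for named genes. The median difference of each list was placed among the medians of 10000 random lists of the same size, drawn from the other genes and matched on mean intensity in 20 bins. A list is described as outside the random lists if its median lay under their 2.5th or over their 97.5th percentile. With 44 lists, 2.2 would lie outside by chance if genes were independent, which members of a pathway are not. The percentile describes these 2 arrays and is not a test of the genotype. The rule named Oma1, the 12 genes with the highest and the 12 with the lowest difference, up to 4 members of each list with the largest absolute difference, Opa1, Ucp1, Lep, Adipoq, Nnt and the sex-linked genes. Genes with automatic locus names were left out of the 12.

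The procedure was tested on simulated data made by permuting the differences of these 2 arrays within intensity bins. Of 200 randomly drawn lists of 15 genes with no shift, 3.5% were outside the random lists on either side. With a shift of 0.2, 90.5% were above them. The permutation removes joint regulation of genes, so these shares do not carry over to lists of a pathway or cell type. Among 200 genes raised 2-fold, 51.5% were counted as at least 2-fold higher, and among those raised 3-fold 98.5% were. The alternatives tried were quantile normalisation, a loess correction of the difference against intensity, centring on the median, the brightest probe set of a gene in place of the mean, a pseudocount of 16, and other intensity filters. Taking list members by their wild-type value was added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.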

Results

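White adipose tissue, the main fat store of the body, was collected from 24-week-old mice after 20 weeks of high-fat diet. Oma1 encodes a protease of the mitochondrial inner membrane that cleaves Opa1, a protein of mitochondrial fusion. The comparison asked which transcripts differed in fat after this diet between the array labelled control and that labelled Oma1-deficient. It rested on 1 control array and 1 Oma1-deficient array, so none of the differences below has a replicate check, and the number of arrays limits the precision of every value. The labels state neither the fat depot nor whether RNA of several mice was pooled on an array.

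The Oma1 probe set read an intensity of 187 in the wild-type array and 155 in the Oma1-deficient array, a log2 difference of -0.27. That was a lower value than for most genes, but 1594 of the 11399 genes above the intensity filter had a still lower difference. Oma1 has 1 probe set on this array, and which part of the transcript was disrupted is not given in the labels, so this value does not check the genotype and the label is taken as given. Opa1 read 757 and 674, a difference of -0.17, equal in size to the SD of 0.17 between probe sets of one gene. The Y-linked genes Eif2s3y, Uty and Kdm5d were present on both arrays, at 659 and 569, 419 and 380, and 215 and 220. Xist, the RNA of the inactive X chromosome, was dim on both, at 59 and 21.

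The 2 arrays were close, with a Pearson correlation of 0.99 across all 35512 probe sets. Of the 11399 genes, 11061 (97.0%) differed by less than 1.5-fold. In the Oma1-deficient array 31 genes were at least 2-fold higher and 28 at least 2-fold lower, and 140 and 198 were at least 1.5-fold higher and lower. The median difference of these genes was -0.06. After quantile normalisation the 1.5-fold split was 169 higher and 147 lower, and after loess 166 and 153, so which direction held more genes depended on the scaling. Outside the named genes, 5127 probe sets with several symbols or none passed the filter, of which 60 were at least 2-fold higher and 115 at least 2-fold lower.

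**Figure D1:**
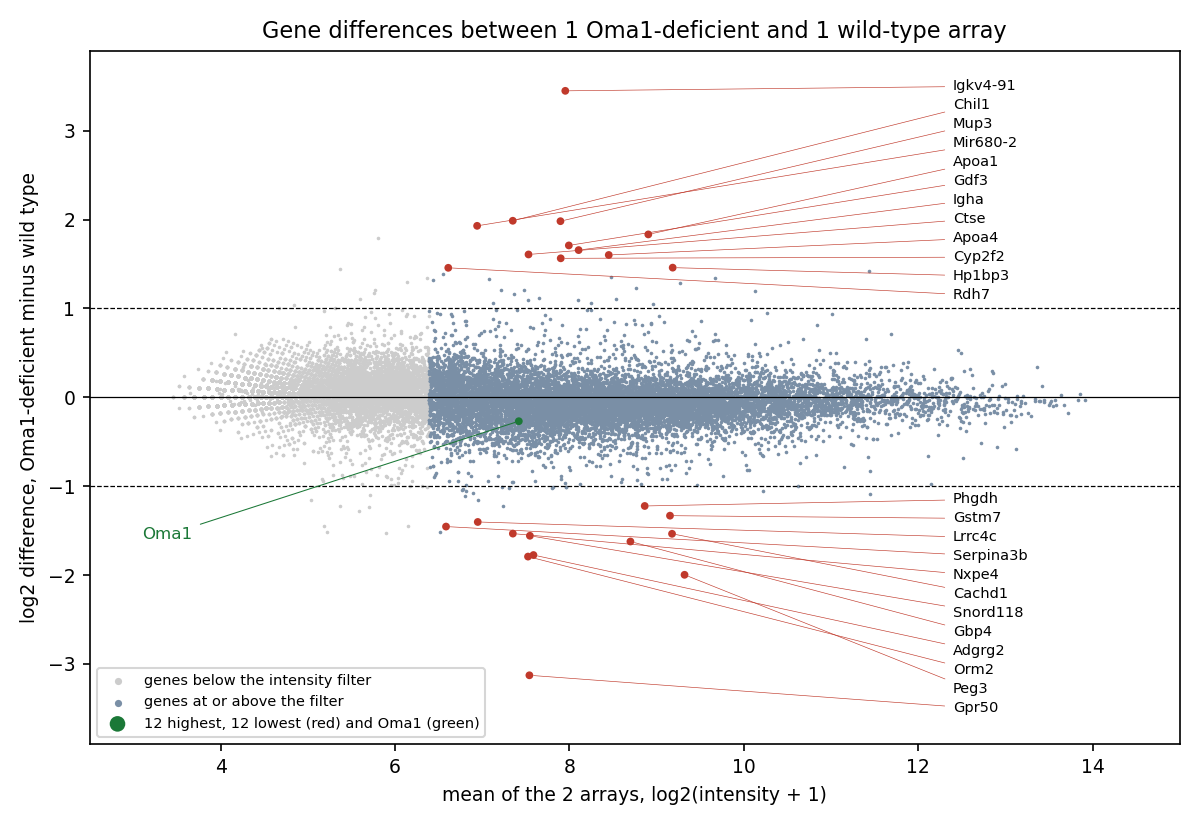
Each point is a gene; the x axis is the mean of both arrays as log2(intensity + 1), the y axis the log2 difference of Oma1-deficient minus wild type, and dashed lines mark 2-fold. Igkv4-91 stands highest at 3.45 and Gpr50 lowest at -3.13, while Oma1 lies at -0.27 among the bulk of the genes.

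The highest difference was that of Igkv4-91, a variable segment of the immunoglobulin kappa light chain, which read 74 in wild type and 818 in Oma1-deficient fat, a difference of 3.45. Igha, the constant region of immunoglobulin A, read 154.2 and 488.2. Chil1, a secreted chitinase-like protein, read 81 and 324, and Gdf3, a ligand of the TGF-beta family, read 140 and 460. Ctse, the aspartic protease cathepsin E, read 105 and 322. The apolipoproteins Apoa1 and Apoa4 read 253 and 904, and 200 and 609. Mup3, a major urinary protein, read 119 and 473, Cyp2f2, a cytochrome P450, 138 and 410, and Rdh7, a retinol dehydrogenase, 58 and 161. Liver markers fixed as a list were also higher, with a median of 0.92. Hp1bp3, a chromatin protein, read 350 and 964, and the microRNA gene Mir680-2 read 62 and 239. In wild type Igkv4-91, Chil1, Mir680-2 and Rdh7 were under the filter intensity of 83. They passed through the Oma1-deficient array, and the size of their difference is uncertain. Immunoglobulin segments and Mup genes have near-identical copies, so their probe sets may take signal from several genes and their identity is uncertain.

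The lowest difference was that of Gpr50, an orphan G protein-coupled receptor, which read 550 in wild type and 62 in Oma1-deficient fat, a difference of -3.13. Peg3, an imprinted zinc finger gene, read 1277 and 319, a difference of -2.00. Orm2, an acute-phase plasma protein, read 342 and 98, and Adgrg2, an adhesion receptor, 355 and 103. Gbp4, a guanylate-binding protein induced by interferon, read 729 and 236. Phgdh, the first enzyme of serine synthesis, read 711 and 304, and Gstm7, a glutathione transferase, 903 and 358. Cachd1 read 985 and 339, Nxpe4 277 and 95, Lrrc4c 200 and 75, and Serpina3b 158 and 57. Snord118, a small nucleolar RNA, read 320 and 108. In the Oma1-deficient array Gpr50, Lrrc4c and Serpina3b were under the filter intensity of 83, so the size of their difference is uncertain.

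Adipocyte genes differed little. Of 17 measured genes of adipocyte identity and adipokines, 13 were lower and 4 higher, all within 1.5-fold, with a median of -0.10 at the 8.95th percentile of random lists. Lep, which encodes leptin, read 6797 and 6375 (-0.09), and Adipoq, which encodes adiponectin, 6832 and 5255 (-0.38). Of 13 lipolysis and lipid droplet genes, 9 were lower and 0 reached 1.5-fold, with a median of -0.13 (percentile 3.56, and 1.91 after loess). Pnpla2, the adipose triglyceride lipase, read 6769 and 5540 (-0.29). In fatty acid and triglyceride synthesis 17 of 23 genes were lower and 0 reached 1.5-fold (median -0.07, percentile 17.35), Pnpla3 with 3375 and 2440 (-0.47) and Mlxipl, the carbohydrate response factor, with 643 and 469 (-0.45) among them.

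Cholesterol synthesis genes were lower as a list. Of 15 measured, 14 were lower and 0 reached 1.5-fold, with a median of -0.20 at the 0.28th percentile. Cyp51 read 561 and 384 (-0.55), Sc5d 2873 and 1993 (-0.53), Lss 1241 and 904 (-0.46), all enzymes of the pathway, and Insig1, which retains its transcription factors in the endoplasmic reticulum, 8059 and 5654 (-0.51).

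Genes of energy metabolism and of mitochondrial dynamics lay inside the random lists. The 33 oxidative phosphorylation genes, 0 of which reached 1.5-fold, had a median of -0.01 (percentile 86.68), which was 0.03 after quantile normalisation. The 21 fatty acid beta-oxidation genes had a median of 0.02 (percentile 95.64); 1 of them, Ehhadh, a peroxisomal enzyme, was at least 1.5-fold lower, at 513 and 333 (-0.62), and Acaa2 read 2897 and 3570 (0.30). The 16 tricarboxylic acid cycle genes (median -0.07, percentile 35.14) and the 13 glycolysis genes (median -0.09, percentile 22.12) held 0 genes past 1.5-fold. The same was true of the 26 genes of mitochondrial dynamics and protein quality control (median -0.08, percentile 34.69), in which Clpx, a subunit of a matrix protease, had the largest difference, at 406 and 318 (-0.35).

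Of 17 thermogenic and brown fat genes 10 were higher, 6 lower and 1 equal, with a median of 0.06 inside the random lists (percentile 87.43). Only 2 were at least 1.5-fold higher, and 0 were at least 1.5-fold lower. Cidea, a lipid droplet protein abundant in brown fat, read 84 and 213 (1.33), and Slc27a2, a fatty acid transport protein, 108 and 195 (0.85). Ucp1, the uncoupling protein of brown fat, was below the intensity filter at 38 and 55 (0.52). With the 11 members above the filter alone the median was 0.18 (percentile 99.93), and with the 12 above it in the wild-type array, a choice added after seeing the data, 0.10 (percentile 98.20). The list fixed for the position of interscapular brown fat lay inside the random lists (10 genes, median 0.09, percentile 79.42). Of its genes 6 were higher, 2 lower and 2 equal, and only 5 passed the filter. Hoxa5 read 175 and 112 (-0.64) and Wt1 178 and 214 (0.26), so the median does not tell the position of the fat.

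Among stress and signalling lists, the 18 targets of the integrated stress response had a median of -0.08 (percentile 34.94). Apart from Phgdh, Sesn2 was at least 1.5-fold lower, at 500 and 324 (-0.62), while Asns, asparagine synthetase, read 1211 and 1598 (0.40). The 15 endoplasmic reticulum chaperones (0.02, above 9500 of the 10000 random lists), 17 oxidative stress genes (-0.02, percentile 67.58), 15 immediate early genes (-0.06, percentile 52.23), 9 glucocorticoid-responsive genes (-0.05, percentile 55.04) and 21 ribosomal protein genes (-0.04, percentile 58.44) lay inside the random lists. Zbtb16, a glucocorticoid-induced transcription factor, read 1178 and 639 (-0.88). For beta-oxidation, chaperones, oxidative stress, ribosomal protein and fibroblast genes the mean and the median of the list had opposite signs.

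Clock genes of opposite phase lay on opposite sides. All 4 measured genes of the Bmal1 phase were lower (median -0.40, percentile 0.54), Arntl, the Bmal1 gene, with 215 and 140 (-0.62) and Nfil3 with 166 and 114 (-0.54). Of 10 genes of the Dbp phase 7 were higher (median 0.17, percentile 99.94, or 0.10 with the brightest probe set of each gene), Dbp with 574 and 838 (0.55) and Nr1d1 with 2828 and 3576 (0.34).

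Macrophage and mast cell markers were higher in the Oma1-deficient array. Of 18 macrophage markers 14 were higher and 1 reached 1.5-fold, with a median of 0.21 (above all 10000 random lists). Fcgr1, an immunoglobulin receptor, read 308 and 503 (0.71), C1qa, a complement subunit, 2167 and 2845 (0.39), and Cd163 243 and 185 (-0.39). The 11 markers of lipid-associated macrophages had a median of 0.08 (percentile 96.92, and 97.51 after quantile normalisation), with Trem2, a lipid receptor, at 1553 and 2241 (0.53). Of 10 mast cell markers 8 were higher and 2 lower, and 4 were at least 1.5-fold higher (median 0.26, percentile 99.98). Only 5 of the 10 passed the filter. The median was 0.16 with a pseudocount of 16 and 0.61 with the members above the filter alone. Of the mast cell proteases, Cpa3 read 282 and 663 (1.23), Mcpt4 215 and 426 (0.98) and Tpsb2 202 and 308 (0.61), while Cma1, at 42 and 67 (0.66), was below the filter. Dendritic cell markers lay inside the random lists (11 genes, 0.07, percentile 89.02), but with the 8 members above the filter alone the median was 0.25 (percentile 99.96). Among them the class II histocompatibility genes H2-Aa and H2-Ab1 read 4674 and 6754 (0.53) and 4857 and 6866 (0.50). Cd209a, also above the filter, went the other way at 560 and 397 (-0.50). Of all 11 dendritic cell markers 7 were higher and 4 lower. The 23 cytokine and chemokine genes had a median of 0.07 (percentile 98.78), which lay inside the random lists after quantile normalisation and after loess. Ccl3 read 651 and 1015 (0.64) and Ccl2 646 and 884 (0.45), while Nos2 read 139 and 101 (-0.46) and Saa3 1270 and 926 (-0.46).

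Other immune lists were lower or inside the random lists. Of 11 B and plasma cell markers 10 were lower (median -0.27, percentile 0.09). With the 7 members above the filter alone the median was -0.28 (percentile 0.97). Cd79a, part of the B cell receptor, read 163 and 75 (-1.11) and Cd79b 437 and 306 (-0.51). Jchain, which joins secreted immunoglobulins, went the other way at 323 and 575 (0.83). So did Igha, which is outside the list, at 154.2 and 488.2, and the immunoglobulin kappa segment described above. The list pools B and plasma cells, so its median does not show that plasma cell transcripts were lower. Of 16 interferon-stimulated genes 14 were lower (median -0.18, percentile 2.14), Gbp3 with 250 and 157 (-0.67) and Ifit3 with 502 and 341 (-0.56), and the list was inside the random lists after quantile normalisation (-0.11, percentile 3.78) and loess. T and NK cell markers (13 genes, -0.10, percentile 7.42) and neutrophil markers (10 genes, 0.06, percentile 54.62) lay inside. Only 2 of the 10 neutrophil markers passed the filter, so their median does not show that neutrophils were equal.

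Endothelial and mesothelial markers were lower. Of 12 endothelial markers 10 were lower and 1 reached 1.5-fold (median -0.34, below all 10000 random lists), with Robo4 at 544 and 347 (-0.65), Gpihbp1, the capillary anchor of lipoprotein lipase, at 1008 and 735 (-0.46) and Kdr, a receptor for vascular endothelial growth factor, at 570 and 427 (-0.42). Of 11 markers of mesothelium, the layer that covers visceral organs, 10 were lower and 3 reached 1.5-fold (median -0.51, below all 10000 random lists), Upk3b with 773 and 455 (-0.76) and Krt19 with 186 and 112 (-0.73). Of 10 pericyte and smooth muscle markers 7 were higher and 3 lower (median 0.14, percentile 99.59). Only Cnn1, a contractile protein of smooth muscle, reached 1.5-fold, at 96 and 201 (1.06), and Notch3, a receptor of mural cells, read 421 and 337 (-0.32). Of 21 extracellular matrix genes 15 were lower and 0 reached 1.5-fold (median -0.15, percentile 0.85), Col4a2 with 1610 and 1147 (-0.49) and Col3a1 with 1724 and 1328 (-0.38), while Timp1, a protease inhibitor, read 482 and 686 (0.51). Preadipocyte and fibroblast markers lay inside the random lists (11 genes, -0.04, percentile 60.89). Of 17 cell cycle genes 13 were lower (median -0.20, percentile 0.22, or -0.13 after quantile normalisation), but 7 were below the intensity filter, and with the other 10 the median was -0.06 (percentile 55.65).

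Markers of other tissues were measured as a check of what the samples held. Of 9 liver markers 8 were higher and 7 reached 1.5-fold (median 0.92, above all 10000 random lists), with Alb, which encodes albumin, at 1692 and 4523 (1.42), Apoa2 at 345 and 715 (1.05), and Apoa1 as above. The 3 measured erythroid genes were higher (median 0.36, percentile 99.46), Alas2, the erythroid enzyme of haem synthesis, with 668 and 855 (0.36). Markers of skeletal muscle (12 genes, 0.05, percentile 45.38) and of epididymis and testis (13 genes, 0.00, percentile 14.96) lay inside the random lists. So did glandular epithelium (11 genes, -0.03, percentile 8.97), nerve (6 genes, 0.14, percentile 90.92) and pancreas (7 genes, 0.07, percentile 59.29). In that order, only 4, 1, 2, 2 and 2 of their genes passed the filter. Their medians therefore cannot show whether such tissue was absent or equal in the 2 samples. Pvalb of the muscle list, at 44 and 110 (1.30), and Adam7 of the epididymis list, at 62 and 21 (-1.52), were below the filter. The 4 sex-linked genes had a median of -0.18 (percentile 9.74), which does not bear on sex, since the list pools Xist with Y-linked genes. The 10 genes known to vary between mouse strains had a median of -0.21 (percentile 0.65), which was -0.04 (percentile 59.76) with the 8 members above the filter and -0.33 (percentile 0.07) with the 9 above it in the wild-type array, the difference being Cd244a at 90 and 65. Trim12a read 230 and 98 (-1.22), Alad 1384 and 2433 (0.81), Alpl 176 and 111 (-0.66) and Nnt 242 and 359 (0.57). The 20 genes next to Oma1 had a median of 0.01 (percentile 34.59), and Pde4b, at 159 and 106 (-0.58), had the largest difference among them. In all, 16 of the 44 lists lay outside the random lists, 7 above and 9 below. The 9 include the strain list, in which 4 genes were higher and 6 lower.

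**Figure D2:**
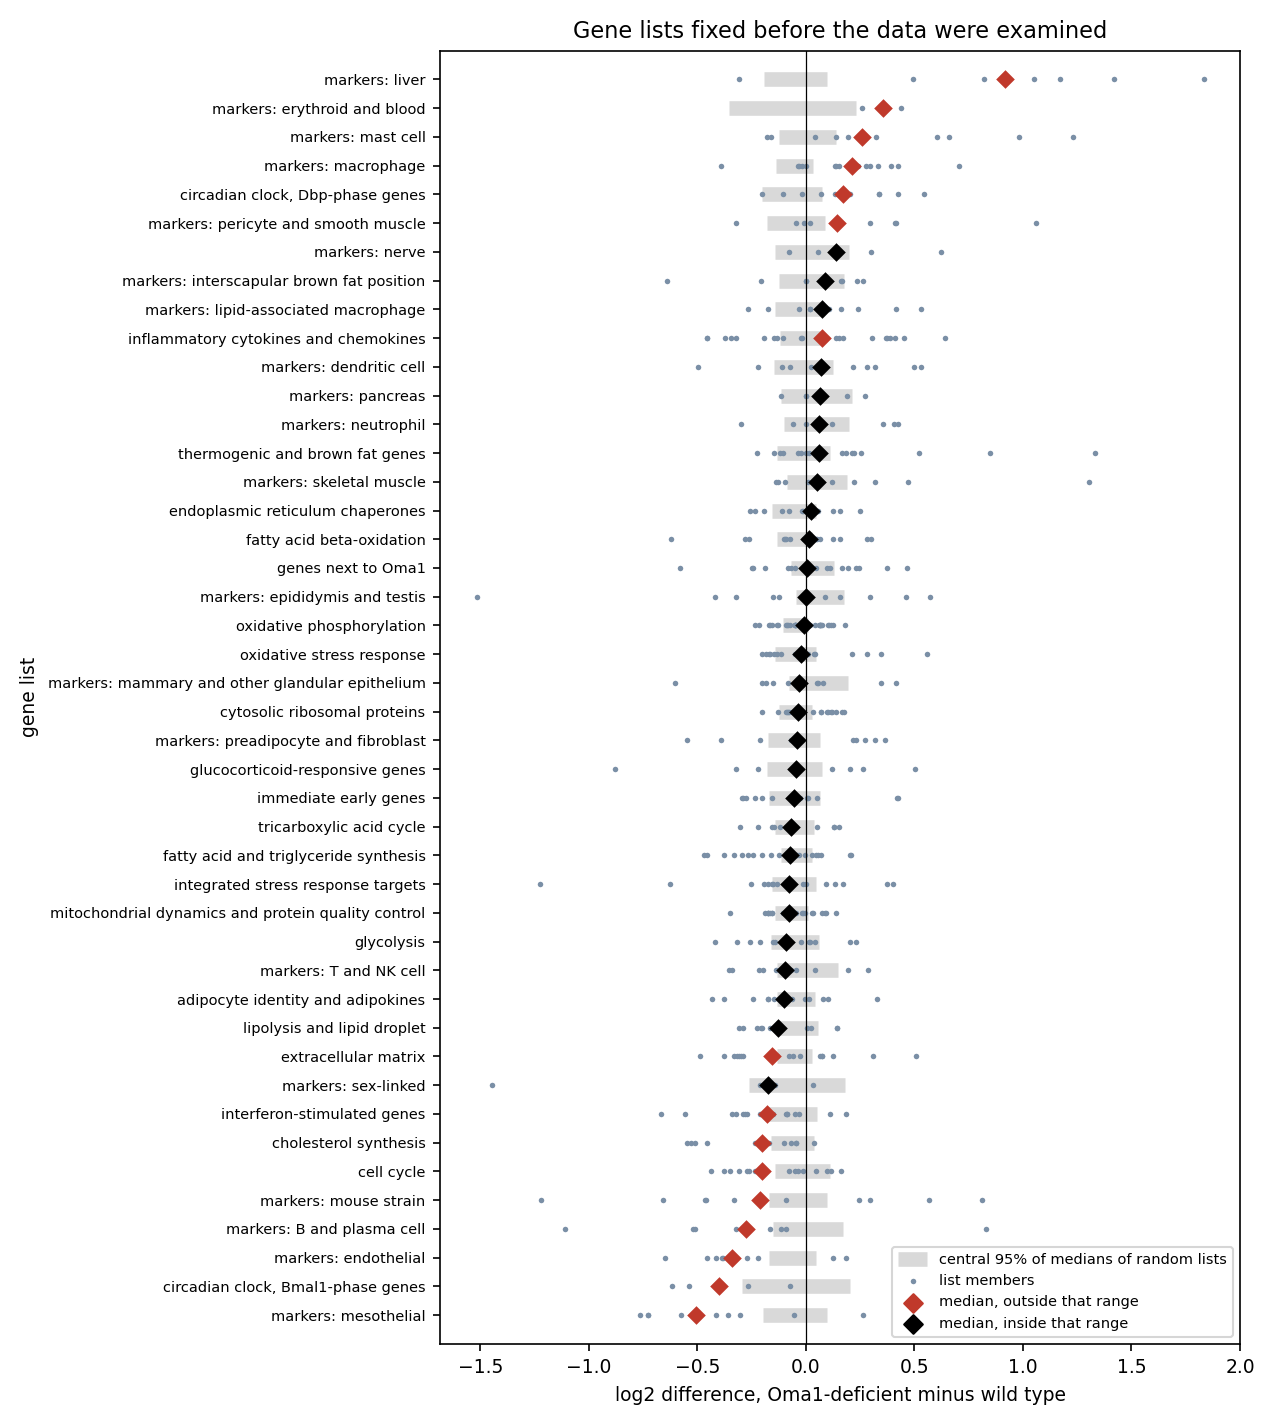
The x axis is the log2 difference of Oma1-deficient minus wild type, with 1 row per gene list; small points are genes, diamonds the list medians, and grey bars the central 95% of medians of random lists. Liver markers have the highest median at 0.92 and mesothelial markers the lowest at -0.51.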

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

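With 1 array per group, no paired analysis or leaving out was possible. All alternatives were planned except choosing members by their wild-type value, added after seeing the data. Centring subtracted 0 and tested nothing. Of the 16 lists outside the random lists, all 16 stayed outside on the same side with the brightest probe set and with a pseudocount of 16, and 14 did with quantile normalisation and with loess, where cytokines and interferon-stimulated genes were the exceptions. With members above the intensity filter alone 13 did, the exceptions being interferon-stimulated genes, cell cycle and strain genes, and 5 lists had under 3 members left. Lists that came to lie outside were lipid-associated macrophages with quantile normalisation, lipolysis and lipid droplet with loess, and thermogenic genes and dendritic cells with either choice of members above the filter. No list outside the random lists and no named gene with a 1.5-fold difference changed sign. The 2-fold counts of 31 and 28 became 11 and 7 with the filter at the upper quartile, and the lower count became 17 with a pseudocount of 16. The 1.5-fold counts of 140 and 198 became 52 and 81 at the upper quartile, and the higher count became 219 with no filter. Other alternatives kept the counts within 1.5 times. Some list medians moved by more than 1 SD of their random lists. With quantile normalisation they were 0.0585 for beta-oxidation, -0.0323 for lipid synthesis, 0.027 for oxidative phosphorylation, -0.0253 for mitochondrial dynamics, -0.0139 for the integrated stress response, -0.114 for interferon-stimulated genes, -0.11 for extracellular matrix and -0.13 for cell cycle. With loess they were 0.0675 for beta-oxidation, -0.14 for cholesterol synthesis, 0.0363 for oxidative phosphorylation, -0.0224 for mitochondrial dynamics, -0.011 for the integrated stress response, -0.11 for interferon-stimulated genes, -0.11 for extracellular matrix, -0.14 for cell cycle and 0.0048 for ribosomal proteins. With the brightest probe set, oxidative phosphorylation had -0.0445 and ribosomal proteins 0.0064. With a pseudocount of 16, mast cell markers had 0.16. With members above the filter alone, the medians were 0.18 for thermogenic genes, -0.0585 for cell cycle, 0.61 for mast cells, 0.25 for dendritic cells, 0.13 for skeletal muscle and -0.0429 for strain genes. That filter uses the mean of both arrays, so a member near it can drop out because it was lower, as Cd244a did. A filter on wild type leans the other way; with it 14 of the 16 stayed outside, interferon-stimulated genes and cell cycle being the exceptions, and medians were -0.0789 for cell cycle, 0.61 for mast cells, 0.216 for dendritic cells and -0.333 for strain genes. Of 199 other named genes, 196 kept their value within the technical SD with the brightest probe set, 188 with a pseudocount of 16, and all 199 with quantile normalisation and loess.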

Other observations

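The tests of genetic background, of the cell shares and of the intensity trend were chosen after the values they bear on had been seen; those of liver, intestine and imprinted genes were set out before their gene lists were looked up. Single genes named here were chosen after their values were seen.

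Imprinted genes other than Peg3 were not described above. Of 18 looked up, 6 were higher and 3 at least 1.5-fold lower. Peg10 read 638 and 353 (-0.85), Zim1, the neighbour of Peg3, 68 and 34 (-0.98, below the intensity filter), Meg3 401 and 258 (-0.63), and Mest, an imprinted gene expressed strongly in expanding fat, 9274 and 6289 (-0.56). Nnat read 3168 and 4129 (0.38) and Slc38a4 98 and 144 (0.55). The hypothesis that imprinted genes were lower as a group was not borne out, since their median was -0.094 (percentile 15.68), above the bound set for it.

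Liver-type transcripts were higher in the Oma1-deficient array. Liver tissue or RNA in that sample is a candidate explanation: 25 hepatocyte enzymes and transporters, which are not secreted and had not been looked at, had a median difference of 0.35, above all 10000 random lists, with 22 higher, and 19 further plasma proteins had 0.34, also above all of them. Not all went this way, as G6pc read 133 and 83 (-0.67), Fah, which wild-type fat also expressed, 3517 and 2864 (-0.30), and the plasma protein Orm2 342 and 98, and 7 of the 9 liver markers and 8 of the 25 enzymes were already at or above the filter intensity in wild-type fat. The enzymes gained a median of 20 intensity units and Cps1, a major liver enzyme, 34, against 2831 for Alb and 651 for Apoa1, and without a liver profile it cannot be said whether these fit 1 share of liver. Intestinal tissue stays open, because 19 intestinal epithelial genes had a median of 0.13 inside the random lists (percentile 86.34) but only 2 of them reached the filter and 15 were higher, Lgals4 with 82 and 150 (0.86) and Vil1 with 33 and 34, and a change of these genes within fat lacking Oma1 stays open and untested.

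Endothelial and mesothelial markers were lower while macrophage and mast cell markers were higher. A lower share of adipocytes in the Oma1-deficient sample, acting alone, would raise all other cell types alike. The macrophage median exceeded the endothelial median by 0.55, against SDs of random medians of 0.04 and 0.05. This restates the pattern, so it bears only on adipocyte share as the sole cause and leaves a part for it open. A trend with intensity shared by all genes is already met by the random lists, which were matched on mean intensity. After loess 4 of the 4 lists stayed outside the random lists on the same side. Given that matching, the loess check could hardly come out otherwise and is no separate evidence. Which part of the fat pad was sampled, how the animals differed apart from genotype, and Oma1 loss itself stay open, as 1 array per group separates none of them. Whether liver tissue or RNA, the candidate named above, also bears on these lists was not tested.

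Genes known to vary between mouse strains differed in both directions. Their median absolute difference was 0.46, above all 10000 random lists, and 0.51 with the 8 members above the filter. This restates the pattern and tests no cause of it, so animals of different genetic background cannot be told apart here from other regulation of these genes, such as that of Alad, an enzyme of haem synthesis, which was higher together with the erythroid gene Alas2. Strain DNA kept next to the disrupted Oma1 could not be settled: the median absolute difference of its 20 neighbours was 0.14, at percentile 51.28, and only 7 of them passed the filter.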
